A study of Mus musculus with 6 samples.

How the data were processed

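Gene expression was measured in mouse muscle satellite cells, which were sorted from 3 mice with a satellite cell-specific knockout of Rpt3 (gene Psmc4) and from 3 control mice. RNA was extracted with TRIzol, and 5 ng of total RNA was amplified over the whole transcriptome and labelled with Cy3, per the labels' protocols. Each mouse gave 1 array. Whether the samples were paired by litter or sorting day is not stated.

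Each scanner file holds linear intensity values of 1 array, per the file headers. The authors' processed signal had been corrected for background and detrended within the array by Agilent Feature Extraction version 10.7.1.1, per the file headers; the submitters' processing notes give version 9.5.1.1. The processed signal carries no normalization between arrays. The deposited value table holds intensity on a linear scale. Its columns have the same quantiles, with a median of 17.7 and a 75th percentile of 83.8 on every array, so it was found to be quantile normalized. It served as an alternative source of values.

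The main values were log2 of the processed signal minus the array's 75th percentile of it. Control spots and spots with outlier flags were left out, and spots of 1 probe were averaged. No spot was saturated: the count was 0 on each array. A probe was tested where it was well above background on all 3 arrays of at least 1 group. Where a gene name had several probes, the brightest one stood for it. Gene names came from the scanner files, whose array annotation is on mouse build mm9. They were updated through transcript accessions with a gene table of assembly GRCm38.p6, of which only names were used. Of 55681 probes, 52937 had 1 gene name and 2744 had none. The accessions of 27235 probes matched the table, and 2838 probes were given a current symbol in place of an older one. After the filter, 25129 probes gave 18658 features. Among 4356 gene names with several tested probes, 1784 had probes with opposite signs, and 9 had probes of opposite signs that each had an unadjusted p under 0.05.

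Knockout and control arrays were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with files read by the data.table package in version 1.17.8. The p-values were adjusted by Benjamini-Hochberg, and the threshold was an adjusted p of 0.05. All tests were 2-sided. Single values were also compared by exact permutation, which for 3 arrays against 3 cannot go below 0.1. Log2 differences are knockout minus control. For a probe not well above background on any array of a group, the fold is a bound. The bright group's mean was set against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

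Before the data were examined, 36 gene lists were fixed for proteasome subunits, protein quality control, stress responses, cell death, the cell cycle, the myogenic lineage and markers of other cell types. Lists with at least 5 tested members, 35 in number, were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Adjusted p-values of lists are over the 35 lists. A count adjusted over the list alone uses the gene p-values of that list's members.

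The rule for named genes, also fixed before the data were examined, took Psmc4, Pax7, Myf5, Myod1, Myog, Trp53, Cdkn1a and Mdm2 always. It took the 8 genes with the largest differences in each direction among those past the threshold, or, as none passed, the 5 with the smallest p in each direction. From each list it took up to 4 members past the threshold adjusted over the list alone, and otherwise up to 2 that did not pass. Some genes that the rule takes from the lists are not reported.

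The share of probes well above background ranged from 44.2% to 57.9% over the arrays. For arrays, the number of replicates limits the precision, and the median standard error of a log2 difference was 0.27. The scripts were tested on simulated data with 18658 features, 3 arrays against 3, and 200 changed genes in 20 simulations. The fit recovered 3.96% of genes changed 2-fold, 67.0% of those changed 4-fold and 90.9% of those changed 8-fold, and 5.20% of its calls were false. A list raised by 0.5 on the log2 scale was called in 20 of 20 simulations at the preset correlation and in 0 of 20 with the estimated one. With a correlation of 0.3 within unchanged lists, 9.15 of 35 lists per simulation were called at the preset correlation and 0 with the estimated one.

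Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, a percentile over detected probes, no filter or a stricter filter on dim probes, outlier flags kept, every probe or the mean of probes, the deposited table, an intensity trend with robust moderation, array weights, an ordinary 2-sample test, the replicate number as a block, the slide row as a block, the arrays of slide row 2 alone, each array left out in turn, other thresholds and other set tests. All 6 arrays lay on 1 slide with 1 scan date, so neither served as a batch.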

Results

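Gene expression was measured in satellite cells, the stem cells of skeletal muscle, sorted from C57BL6 mice that lack Rpt3 in these cells and from control mice. Rpt3, the product of Psmc4, is an ATPase of the 19S regulatory particle of the proteasome, the complex that degrades ubiquitin-tagged proteins. RNA of 3 knockout and 3 control mice was hybridized to 1 Agilent array each. Of the non-control probes, 57.9%, 51.7% and 44.2% were well above background on knockout arrays 1, 2 and 3, and 53.6%, 53.03% and 53.2% on control arrays 1, 2 and 3. Knockout 1 and knockout 2 lay in slide row 1, and knockout 3 and the 3 control arrays lay in slide row 2. Values with slide row as a block and within slide row 2 therefore both rest on knockout 3 alone against the 3 controls, and their p-values assume that this lone array varies like the others. Of these 2 fits, only the one within slide row 2 filtered the probes anew, so the 2 can differ. Fits that left out arrays also chose probes anew, so a list's members and a gene's probe can differ there from those reported. Knockout 3 stood apart from the other arrays: its score on the first principal component, which held 29.5% of the variance, was 71.2, and the others lay between -22.4 and -2.73. On the second component, with 26.3% of the variance, knockout 1 and 2 lay at 37.5 and 33.7, and control 2 and 3 at -37.0 and -40.7. Knockout 3, at -1.78, and control 1, at 8.34, lay between them, so the groups overlapped. Across genes, which are not independent replicates, Pearson's r between arrays ranged from 0.952 to 0.976.

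The comparison of knockout with control cells asks which transcripts differ in satellite cells without Rpt3. The targeted gene, Psmc4, had a lower signal in all 3 knockout samples than in any control sample. Its normalized log2 signal was 2.004, 2.02 and 1.52 in knockout 1, 2 and 3, and 2.89, 2.58 and 2.84 in control 1, 2 and 3. The mean was 1.85 ± 0.28 (SD, n = 3) in knockout and 2.77 ± 0.16 (SD, n = 3) in control cells. The log2 difference was -0.92 with a standard error of 0.23, which left 52.8% of the control signal. It did not pass the threshold over all genes (limma, adjusted p = 0.399), and the exact permutation p was 0.1, the smallest that 3 arrays against 3 allow. With slide row as a block the difference was -1.25 (adjusted p = 0.236), and within slide row 2 it was -1.25 (adjusted p = 0.316). Over all alternatives it lay between -1.25 and -0.70, with adjusted p from 0.0675 to 0.801. The array holds 1 probe for Psmc4, A_52_P10254 for transcript NM_011874, with the sequence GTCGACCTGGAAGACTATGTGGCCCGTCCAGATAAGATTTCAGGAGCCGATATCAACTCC. Its 60 bases span 242 bp of chromosome 7 in build mm9, from 28827132 to 28827373, so it crosses a splice junction. The labels do not say which part of the gene was deleted. If the probe lies outside that part, its signal checks nothing about the deletion.

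Beside the lower Psmc4, the knockout cells had higher mean signals of the other proteasome subunits and lower ones of genes of DNA replication and mitosis, as lists tested at a preset correlation. The 14 subunits of the 20S core were 2.16-fold higher on average and the 18 other 19S subunits 1.88-fold higher, with log2 means of 1.11 and 0.91 that were 0.68 and 0.55 with slide row as a block. The 17 measured mitosis genes had a log2 mean of -1.18, which was -0.37 with normexp background correction. With an estimated correlation 0 lists passed (adjusted p = 0.327 for both proteasome lists and 0.273 for mitosis), and 0 single genes passed over all genes in either direction. The muscle regulator Myf5 was not well above background in any knockout sample, and Pax7 and Myod1 had log2 differences of 0.17 and 0.00.

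By limma, 0 of 18658 features were higher and 0 were lower at an adjusted p under 0.05, and the smallest adjusted p was 0.0649. At an unadjusted p under 0.05, 534 features were higher and 814 lower, together 7.22% where 5% fall by chance. An ordinary 2-sample test also called 0 features, with 1036 at an unadjusted p under 0.05. In 2003 features, or 10.74%, the groups did not overlap, beside a chance share of 10%. The genes with the smallest p in each direction, none of which passed, were as follows. Ereg, which encodes the growth factor epiregulin, was not well above background in any knockout sample and was at least 5.77-fold lower there (adjusted p = 0.0649; chromosome 5 of mm9, 91522553 to 91522612). Olfr591, an olfactory receptor gene, was at least 2.61-fold lower, with the same adjusted p. Pimreg, a gene of proliferating cells, was at least 3.58-fold lower (adjusted p = 0.108), and Nusap1, which encodes a protein of the mitotic spindle, at least 4.01-fold lower (adjusted p = 0.148). The probe that stood for Inpp4a, a phosphoinositide phosphatase gene, was at least 2.24-fold lower (adjusted p = 0.108), but another probe of that gene was above background in knockout cells. With normexp background correction the log2 differences of these 5 genes lay between -1.001 for Ereg and -0.40 for Inpp4a, and none passed. In the other direction, Hspb8, which encodes a small heat shock protein of chaperone-assisted autophagy, differed by 3.08 (SE 0.47), or 8.43-fold (adjusted p = 0.184; chromosome 5, 116859063 to 116859122). Impact, an inhibitor of the amino acid sensor GCN2, was 2.95-fold higher (log2 difference 1.56, SE 0.21, adjusted p = 0.157). Cpt1a, the gatekeeper of fatty acid entry into mitochondria, differed by 1.59 (SE 0.22, adjusted p = 0.164). Gas8, a component of motile cilia, differed by 1.51 (SE 0.22, adjusted p = 0.184), and Psmc6, a sister ATPase of Rpt3, by 1.32 (SE 0.21, adjusted p = 0.206). With normexp Hspb8 differed by 1.96 and passed (adjusted p = 0.0474), while Cpt1a, at 0.97, and Gas8, at 0.62, did not.

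All 14 genes of the 20S core, the barrel that holds the proteolytic sites, had higher means in knockout cells. Adjusted over the list alone, 13 rose and 0 fell, and over all genes 0 passed; Psma3 (0.42, SE 0.25), named after its value was seen, was the one that did not. Psmb3 differed by 1.64 (SE 0.28), Psma1 by 1.57 (SE 0.28), Psma5 by 1.40 (SE 0.26) and Psmb2 by 1.49 (SE 0.30). The list's mean signal was 4.02 ± 0.38 (SD, n = 3) in knockout and 2.90 ± 0.13 (SD, n = 3) in control cells, a difference of 1.11 (camera, adjusted p = 5.36e-19; adjusted p = 0.327 with an estimated correlation). Knockout 3 lay nearest to the controls: relative to the mean of all arrays, the list stood at 0.85, 0.70 and 0.12 in knockout 1, 2 and 3 and at -0.41, -0.67 and -0.59 in the controls. For knockout 3 alone against the controls, the difference was 0.68 (adjusted p = 0.000176 with slide row as a block and 0.00217 within slide row 2).

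The 18 other subunits of the 19S particle, which binds and unfolds substrates, moved the same way. Among its members, adjusted over the list alone, 16 rose and 0 fell, and over all genes 0 passed; Psmd13 (0.68, SE 0.39) and Sem1 (0.18, SE 0.23), named after their values were seen, did not pass. Psmc6 differed by 1.32 (SE 0.21), Psmd3 by 1.56 (SE 0.29), Psmd1 by 1.495 (SE 0.30) and Psmd4, a ubiquitin receptor, by 1.05 (SE 0.22). The mean difference was 0.91 (camera, adjusted p = 7.43e-19; adjusted p = 0.327 with an estimated correlation). It was 0.55 with slide row as a block (adjusted p = 0.000819) and 0.55 within slide row 2 (adjusted p = 0.00483). Both lists kept their call without each single array. Markers of neutrophils stood at 0.98, 0.91 and -0.56 in knockout 1, 2 and 3, so they also were highest in the samples with the most proteasome mRNA. In knockout 3, however, they lay below control 1 (-0.26) and control 2 (-0.40). The 4 measured markers of red blood cells stood at 1.16, 0.87 and 0.35 in knockout 1, 2 and 3. In control 1, 2 and 3 these red blood cell markers stood at 0.11, -0.92 and -1.57. They thus lay above every control and fell in the same knockout order as the proteasome lists.

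**Figure D1:**
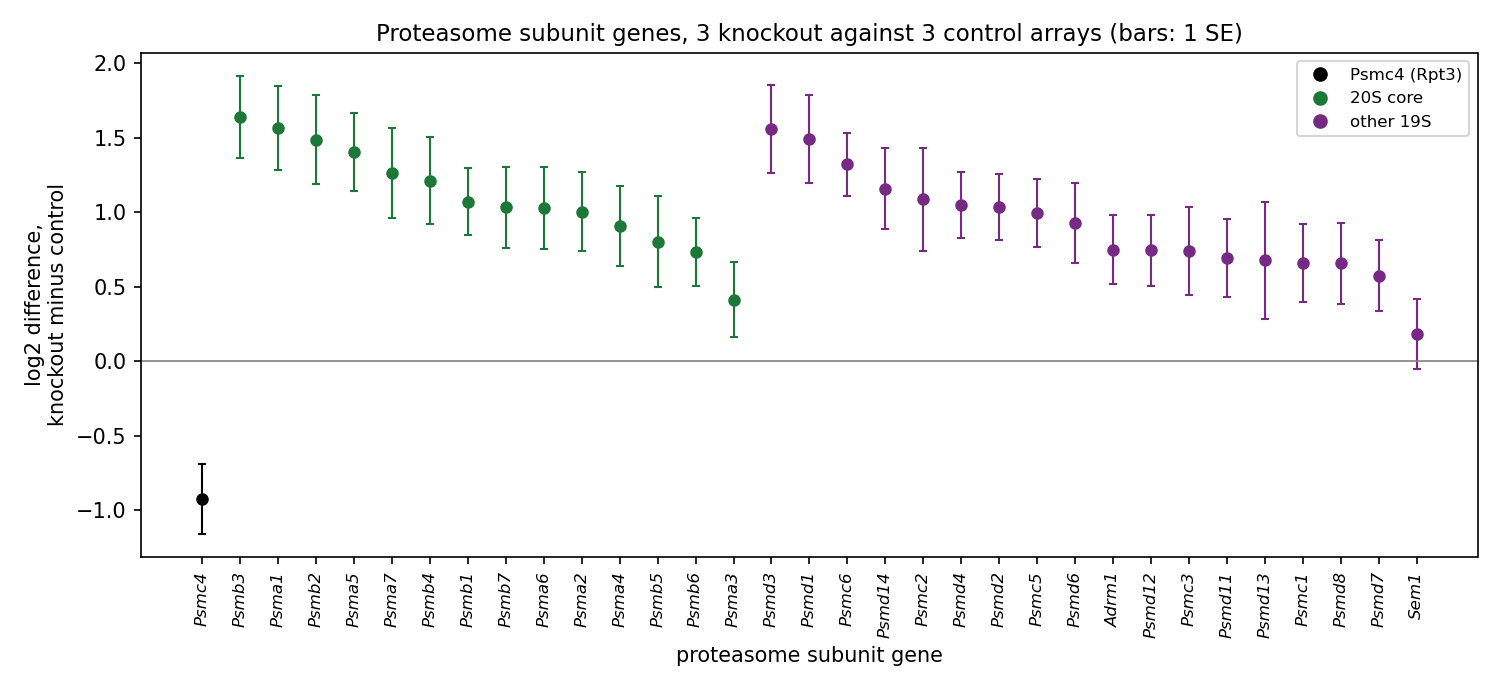
Log2 difference of each proteasome subunit gene, knockout minus control, from 3 arrays against 3, with bars of 1 standard error. Psmc4 lies at -0.92, and the 32 other subunits lie above 0, from 0.18 for Sem1 to 1.64 for Psmb3.

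The lists of immunoproteasome and activator genes and of assembly factors did not pass the threshold. The 6 measured immunoproteasome and activator genes had a mean difference of 0.32 (adjusted p = 0.157), and adjusted over the list alone 0 rose and 0 fell. Psmb8 (0.63, SE 0.46) and Psme4 (0.56, SE 0.43) did not pass. Without control 1 this list was called, at 0.48 (adjusted p = 0.0171). The 7 measured proteasome assembly factors had a mean of -0.08 and a median of 0.09 (adjusted p = 0.702), and 0 passed adjusted over the list alone. Psmg1 (-0.69, SE 0.26) and Psmg2 (-0.61, SE 0.39, above background in 1 of 3 knockout samples) did not pass.

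Among 23 genes of ubiquitin, its shuttles and the segregase that extracts tagged proteins, 3 rose and 0 fell adjusted over the list alone, and over all genes 0 passed. Nploc4 differed by 1.24 (SE 0.25), Vcp, which encodes the segregase p97, by 1.03 (SE 0.24), and Zfand2a, a stress-induced partner of the proteasome, by 1.45 (SE 0.35). The list's mean was 0.33 (camera, adjusted p = 0.00135; adjusted p = 0.505 with an estimated correlation). The call ended without knockout 2, at 0.23 (adjusted p = 0.0644), and with slide row as a block, at 0.05 (adjusted p = 0.896). Within slide row 2 the mean was 0.05, and the test's direction was lower (adjusted p = 0.997).

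Genes of the oxidative stress response under NRF2 were higher as a list, with a mean difference of 0.44 over 20 genes (camera, adjusted p = 5.21e-06; adjusted p = 0.443 with an estimated correlation). Adjusted over the list alone, 0 rose and 0 fell, as over all genes. Me1, which encodes malic enzyme, differed by 1.62 (SE 0.43) and the peroxidase gene Prdx1 by 0.72 (SE 0.22), and neither passed. The list kept its call without each single array, but with slide row as a block its mean was 0.19 (adjusted p = 0.243), and within slide row 2 it was 0.19 (adjusted p = 0.376). The 17 cytosolic heat shock genes had a mean of 0.33 (camera, adjusted p = 0.0333; adjusted p = 0.745 with an estimated correlation). Only Hspb8, at 3.08, rose adjusted over the list alone, with 0 that fell and 0 past the threshold over all genes. The list stood at 0.59 in knockout 2, and at -0.08 and -0.01 in knockout 1 and 3. Its call ended without knockout 2, at 0.12 (adjusted p = 0.999), without control 1, at 0.33, and without control 3, at 0.28. It also ended with quantile normalization, at 0.31 (adjusted p = 0.0669), and in the deposited table, at 0.27 (adjusted p = 0.120). Once slide row was a block the mean was 0.16 (adjusted p = 0.948), and within slide row 2 it was 0.16 with a test direction of lower (adjusted p = 0.997).

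The 21 measured genes of the integrated stress response under ATF4 had a mean of 0.19 (camera, adjusted p = 0.0255; adjusted p = 0.410 with an estimated correlation). Among its members, adjusted over the list alone, 0 rose and 0 fell, as over all genes. Sesn2, a stress-induced inhibitor of growth signalling that is also a p53 target, differed by 0.81 (SE 0.21) and Vldlr by 0.68 (SE 0.21), and neither passed. The call ended without knockout 1, at 0.14, without knockout 2, at 0.17, without control 2, at 0.15, and without control 3, at 0.19. Fitted with slide row as a block the mean was 0.05 (adjusted p = 0.762), and within slide row 2 it was 0.05 (adjusted p = 0.829). The unfolded protein response of the endoplasmic reticulum, with 18 genes, had a mean of 0.04 and a test direction of lower (adjusted p = 0.989), and with slide row as a block the list was lower, at -0.23 (adjusted p = 0.0391). Adjusted over the list alone, 0 passed, among them Hyou1 (1.26, SE 0.68) and Sel1l (-0.36, SE 0.25).

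Genes under p53, the tumour suppressor that answers DNA damage and other stress, had a mean difference of 0.22 over 28 genes (camera, adjusted p = 0.0147; adjusted p = 0.481 with an estimated correlation). Among its members, adjusted over the list alone, 0 rose and 0 fell, as over all genes. Of the 28, 21 were above 0 and 7 below. Sesn2 (0.81, SE 0.21), the nuclease gene Aen (0.91, SE 0.24) and, in the other direction, Pmaip1 (-0.78, SE 0.22) had the smallest p and did not pass. Trp53, the gene of p53 itself, differed by 0.69 (SE 0.28, adjusted p = 0.661), the cell cycle inhibitor Cdkn1a by 0.63 (SE 0.24, adjusted p = 0.618) and Mdm2, the p53 ligase, by 0.64 (SE 0.24, adjusted p = 0.608). With slide row as a block these were 0.29, 0.49 and 0.41. Cdkn1a has 2 other probes, and was 0.34 with the mean of probes. Another probe stood for it without knockout 2, at 0.12, within slide row 2, at 0.15, and without knockout 3 and control 1, at -0.31. The last alternative was chosen after seeing the data. These 3 values differ by probe as well as by array. The probe reported above lay between 3.87 and 4.24 in the knockout samples and between 3.11 and 3.67 in the controls. The list's call ended without knockout 1, at 0.16, without knockout 2, at 0.17, and without control 3, at 0.16, and without knockout 3 the mean was 0.35. In a fit with slide row as a block its mean was 0.01 (adjusted p = 0.956), and within slide row 2 it was 0.00 with a test direction of lower (adjusted p = 0.843).

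Cell death genes outside the p53 list showed no shift past the threshold. The 14 measured pro-apoptotic genes had a mean of 0.01, or -0.13 with slide row as a block, and a median of -0.07 (adjusted p = 0.647), with 0 past the threshold adjusted over the list alone. Casp12 (1.51, SE 0.56, above background in 1 of 3 control samples) did not pass. The 9 anti-apoptotic genes had a mean of 0.00, or -0.41 with slide row as a block, and a median of -0.02 (adjusted p = 0.999), with 0 past the threshold adjusted over the list alone. Cflar (0.26, SE 0.27) and Xiap (-0.31, SE 0.37) did not pass.

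Genes of mitosis were lower in knockout cells. Of 17 measured G2/M genes, 12 had lower and 5 higher means, and adjusted over the list alone 8 fell and 0 rose, with 0 past the threshold over all genes. Nusap1 was at least 4.01-fold lower. Birc5, which encodes the mitotic protein survivin, fell by 1.66 on the log2 scale (SE 0.28), the spindle factor gene Tpx2 by 2.41 (SE 0.43, above background in 1 of 3 knockout samples) and the midzone gene Prc1 by 2.70 (SE 0.50, above background in 2 of 3). With normexp background correction these 3 differed by -1.02, -0.66 and -1.05. Plk1 (0.18), Cdk1 (0.14), Ccnb1 (0.02), Cenpe (0.48) and Ckap2 (0.48), named after their values were seen, were the 5 with higher means, and none passed. The list's mean was -1.18, with a median of -1.57 (camera, adjusted p = 4.14e-08; adjusted p = 0.273 with an estimated correlation). It stood at -0.45, -0.91 and -0.41 in knockout 1, 2 and 3, and at 0.35, 0.66 and 0.76 in control 1, 2 and 3. It kept its call without each single array. For knockout 3 alone against the controls, the mean was -0.997 (adjusted p = 0.0170 with slide row as a block and 0.0119 within slide row 2). Over only the 9 members above background on all 6 arrays, a filter that drops genes whose lower level took them below background, the mean was -0.27 and the call ended (adjusted p = 0.172), and with normexp background correction the mean was -0.37 and the call stayed (adjusted p = 2.32e-07).

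The 20 measured genes of G1/S and DNA replication were lower by a mean of -0.40 (camera, adjusted p = 0.000545; adjusted p = 0.273 with an estimated correlation). Adjusted over the list alone, 2 fell and 0 rose, and over all genes 0 passed. Uhrf1, which maintains DNA methylation at replication, fell by 1.19 on the log2 scale (SE 0.21), and Rrm2, a subunit of ribonucleotide reductase, by 0.86 (SE 0.21). The list kept its call without each single array, with slide row as a block, at -0.63 (adjusted p = 0.00168), and within slide row 2, at -0.55 (adjusted p = 0.00483). With normexp background correction the mean was -0.23, over members above background on all 6 arrays it was -0.26, and the list stayed called in both. The 6 measured inhibitors of cyclin-dependent kinases and pocket proteins had a mean of -0.21 (adjusted p = 0.218), with 0 past the threshold adjusted over the list alone. Cdkn2c (-0.44, SE 0.26) and the retinoblastoma gene Rb1 (-0.33, SE 0.32) did not pass.

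**Figure D2:**
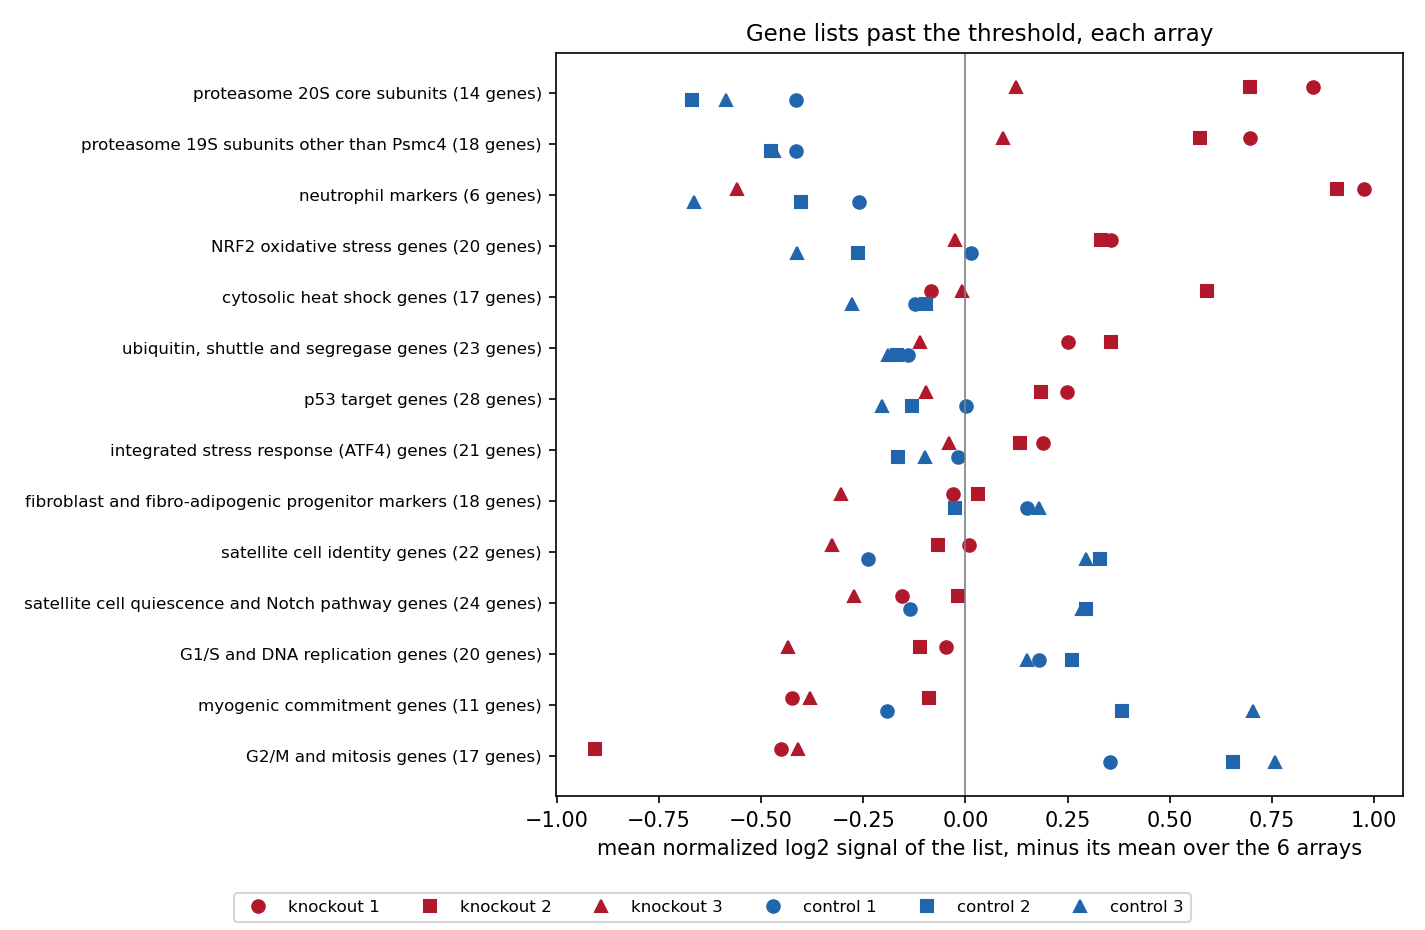
Mean normalized log2 signal of each of the 14 gene lists past the threshold, minus its mean over the 6 arrays, for each knockout (red) and control (blue) array. The 20S core genes lie between 0.12 and 0.85 in knockout and between -0.67 and -0.41 in control, and the G2/M genes between -0.91 and -0.41 in knockout and between 0.35 and 0.76 in control.

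Among the satellite cell identity genes only Myf5 passed, and only adjusted over the list alone. Myf5, a regulator that commits cells to the muscle lineage, was not well above background in any knockout sample and was at least 2.23-fold lower there (adjusted p = 0.184 over all genes). With normexp background correction, which compresses weak signals, its log2 difference was -0.37 (adjusted p = 0.896), within a range of -2.24 to -0.37 over all alternatives. Pax7, the transcription factor that marks satellite cells, differed by 0.17 (SE 0.34, adjusted p = 0.984; above background in 2 of 3 knockout samples), and by -0.16 with slide row as a block. Myod1, which drives activation, differed by 0.00 (SE 0.22, adjusted p = 0.999). Of 22 satellite cell identity genes, 1 (Myf5) fell and 0 rose adjusted over the list alone, and 0 passed over all genes; Fgfr4, a receptor gene of the lineage named after its value was seen, was at -0.90 (SE 0.26). The list was lower by a mean of -0.26 (camera, adjusted p = 0.0147; adjusted p = 0.591 with an estimated correlation). The call ended without knockout 3, at -0.16, without control 2, at -0.16, without control 3, at -0.17, and with array weights, at -0.23 (adjusted p = 0.0513), and without control 1 the mean was -0.44. Control 1 stood at -0.24, near the knockout samples, and control 2 and control 3 at 0.33 and 0.30. Once slide row was a block the mean was -0.46 (adjusted p = 0.0170), and within slide row 2 it was -0.46 (adjusted p = 0.0119).

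The 24 measured genes of quiescence and the Notch pathway, which keep satellite cells at rest, were lower by a mean of -0.30 (camera, adjusted p = 0.00135; adjusted p = 0.481 with an estimated correlation). Among its members, adjusted over the list alone, 0 rose and 0 fell, as over all genes. Calcr, the calcitonin receptor gene, differed by -1.04 (SE 0.28) and Hes6 by -0.52 (SE 0.23), and neither passed. The call ended without control 2, at -0.22, and without control 3, at -0.22, and control 1 again stood near the knockout samples, at -0.14; without it the mean was -0.46. Fitted with slide row as a block the mean was -0.42 (adjusted p = 0.0170), and within slide row 2 it was -0.42 (adjusted p = 0.0119). The 11 measured genes of myogenic commitment had a mean of -0.60 and a median of -0.17 (camera, adjusted p = 0.0374; adjusted p = 0.481 with an estimated correlation). Adjusted over the list alone, 1 fell and 0 rose, and over all genes 0 passed: Chrna1, an acetylcholine receptor subunit gene, fell by 2.22 on the log2 scale (SE 0.54, above background in 1 of 3 knockout samples), and differed by -0.50 with normexp.

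Myog, which drives differentiation, differed by -3.03 with a standard error of 1.04 (adjusted p = 0.576). Its normalized log2 signal was -0.63, 2.93 and 4.08 in control 1, 2 and 3 and -1.12, -0.52 and -1.08 in knockout 1, 2 and 3, so the difference rested on control 2 and control 3. Without control 1 the set of probes in the commitment list differed, and the mean was -1.29. The call of this list ended without knockout 1, at -0.53, knockout 3, at -0.45, control 2, at -0.51, and control 3, at -0.39. It ended as well with slide row as a block, at -0.68 (adjusted p = 0.440), within slide row 2, at -0.68 (adjusted p = 0.235), with normexp, at -0.28, with array weights, at -0.48, with the mean of probes, at -0.57, and over members above background on all 6 arrays, at -0.45. The 17 measured genes of mature muscle fibres had a mean of -0.03 (adjusted p = 0.702), with 0 past the threshold adjusted over the list alone. Myl2 (-1.03, SE 0.54) and Pgam2 (0.58, SE 0.45) did not pass.

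**Figure D3:**
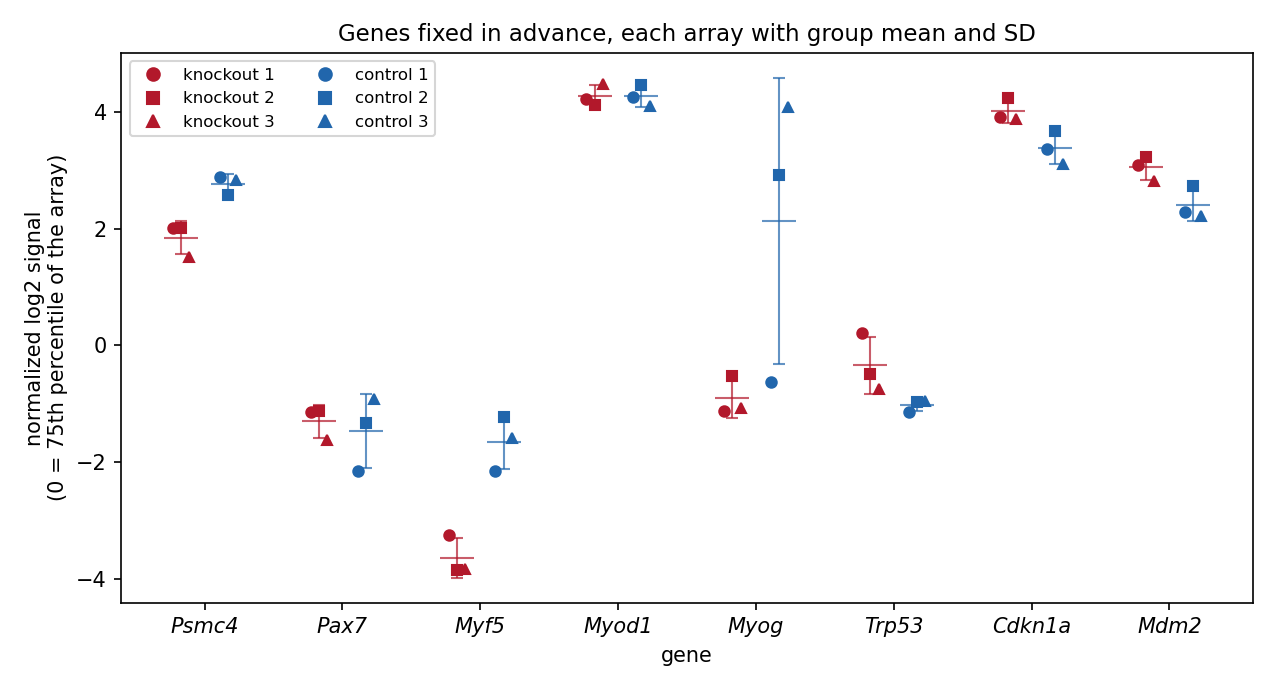
Normalized log2 signal of 8 genes chosen in advance on each of 3 knockout (red) and 3 control (blue) arrays, where 0 is the array's 75th percentile; lines show the group mean and bars the SD. Psmc4 averages 1.85 in knockout and 2.77 in control, and Myog ranges from -0.63 to 4.08 among the controls.

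Markers of other cell types differed between samples. Hemoglobin genes of red blood cells were higher in knockout samples: Hba-a1 rose by 1.88 (SE 0.44) and Hbb-bt by 2.73 (SE 0.88, above background in 1 of 3 control samples; 0.61 with normexp), adjusted over the list alone. The erythroid list, with 4 measured members, was too short for the list test, and its mean difference was 1.59; adjusted over the list alone 2 rose and 0 fell, and over all genes 0 passed. The 6 measured neutrophil markers were higher by 0.88 as a list (camera, adjusted p = 0.0354; adjusted p = 0.410 with an estimated correlation), with 0 past the threshold adjusted over the list alone. Elane (0.74, SE 0.40) and Mmp8 (0.95, SE 0.54), each above background in 2 of 3 control samples, did not pass. Without knockout 3 the set of probes differed from the 6 markers above, and the mean was 1.82. The neutrophil call ended without knockout 1, at 0.62, knockout 2, at 0.65, control 2, at 0.76, and control 3, at 0.83. It also ended with quantile normalization, at 0.84, in the deposited table, at 0.83, and with no filter on dim probes, at 0.65. With slide row as a block the mean turned to -0.12 (adjusted p = 0.896), and within slide row 2 it was -0.12 (adjusted p = 0.720).

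The 18 markers of fibroblasts and fibro-adipogenic progenitors, the connective tissue cells of muscle, were lower by a mean of -0.20 (camera, adjusted p = 0.0268; adjusted p = 0.481 with an estimated correlation), with 0 past the threshold adjusted over the list alone or over all genes. Col1a1 (-0.71, SE 0.27) and Postn (-0.67, SE 0.25) did not pass. The call ended without knockout 3, at -0.10, without control 1, at -0.18, without control 3, at -0.16, and with array weights, at -0.09. In a fit with slide row as a block the mean was -0.41 (adjusted p = 0.0170), and within slide row 2 it was -0.41 (adjusted p = 0.0187). The 14 endothelial markers had a mean of 0.28 (adjusted p = 0.253), but single arrays differed widely: control 1 stood at 1.003 and knockout 3 at -0.75. Without control 1 the endothelial list was higher, by 0.85 (adjusted p = 1.48e-05), and without knockout 3 by 0.71 (adjusted p = 0.0128), but with slide row as a block its mean turned to -0.61 (adjusted p = 0.175), as it did within slide row 2 (adjusted p = 0.164). Tek (0.44, SE 0.38) and Sox17 (0.74, SE 0.78) did not pass.

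The other marker lists did not pass the threshold, and none of their members did adjusted over the list alone. The 8 measured macrophage markers had a mean of 0.38 (adjusted p = 0.268), with C1qb at 0.81 (SE 0.32) and Ctss at 1.09 (SE 1.02, above background in 2 of 3 control samples). Without knockout 3 the set of probes differed, and the macrophage list was higher, by 1.38 (camera, adjusted p = 0.00143). With slide row as a block the mean of the 8 markers turned to -0.35. The 7 lymphocyte markers had a mean of 0.37 (adjusted p = 0.0906), with Cd79a at 0.72 (SE 0.28) and Lck at 0.43 (SE 0.30), and without control 1 they were higher, by 0.58 (adjusted p = 0.00856). The 11 markers of pericytes and smooth muscle had a mean of 0.14 (adjusted p = 0.470), with Cnn1 at 0.55 (SE 0.37) and Rgs5 at 0.71 (SE 0.60). The 11 Schwann cell markers had a mean of 0.07 (adjusted p = 0.702), with Sox10 at 0.47 (SE 0.41). Without knockout 3 they were higher, by 0.34 (adjusted p = 0.0296), and with slide row as a block lower, at -0.49 (adjusted p = 0.0379). The 7 adipocyte markers had a mean of -0.12, or 0.01 with slide row as a block, and a median of 0.02 (adjusted p = 0.806), with Adipoq at -1.37 (SE 0.65) and Pparg at 0.78 (SE 0.53).

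The remaining lists covered protein turnover, metabolism and inflammation, and none of the 8 passed. In the 26 measured autophagy and lysosome genes, the mean was 0.12 (adjusted p = 0.127), and 0 members passed adjusted over the list alone. Sqstm1, which encodes the autophagy receptor p62, differed by 0.79 (SE 0.20), but by 0.14 with the mean of its probes, and Gabarapl1 by 0.66 (SE 0.23). Without knockout 3 the autophagy list was higher, by 0.30 (adjusted p = 0.000600), and with slide row as a block its mean turned to -0.15 (adjusted p = 0.325). The 9 muscle atrophy ligase genes had a mean of -0.16 (adjusted p = 0.221), and 1 fell and 0 rose adjusted over the list alone, with 0 past the threshold over all genes: Cblb, a ubiquitin ligase gene, fell by 0.78 on the log2 scale (SE 0.20). The 5 metallothionein and zinc transport genes had a mean of -0.27 (adjusted p = 0.288), with Slc39a10 at -0.57 (SE 0.27) and Mt3 at -0.77 (SE 0.58, above background in 2 of 3 knockout samples). Once slide row was a block this list was lower, at -0.90 (adjusted p = 0.0170).

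Of the inflammatory lists, the 14 NF-kappaB targets had a mean of 0.15 (adjusted p = 0.461), with Nfkb2 at 0.36 (SE 0.22) and Il1b at 0.28 (SE 0.30). Their direction depended on the arrays: the list was higher without knockout 3, at 0.60 (adjusted p = 0.00527), and without control 1, at 0.56 (adjusted p = 0.00152), and lower with slide row as a block, at -0.62 (adjusted p = 0.0391), and within slide row 2, at -0.62 (adjusted p = 0.0224). The 13 type I interferon genes had a mean of 0.19 (adjusted p = 0.465), with Irf9 at -0.61 (SE 0.24) and Ifi35 at 0.62 (SE 0.26), and were higher without control 1, by 0.49 (adjusted p = 0.00412), with a mean of -0.14 with slide row as a block (adjusted p = 0.634). The 19 immediate early and dissociation-associated genes, which respond to cell isolation, had a mean of -0.07 (adjusted p = 0.361), with Junb at 0.48 (SE 0.23) and Fos at -0.48 (SE 0.23), and were lower with slide row as a block, at -0.29 (adjusted p = 0.0219). The 32 oxidative phosphorylation genes had a mean of 0.07 (adjusted p = 0.361), with Uqcrfs1 at 0.62 (SE 0.29) and Ndufa4 at 0.40 (SE 0.28), and without knockout 3 were higher, by 0.20 (adjusted p = 0.00910), with a mean of -0.19 with slide row as a block (adjusted p = 0.106). The 34 ribosomal protein genes had a mean of 0.08 (adjusted p = 0.213), with Rpl27 at 0.28 (SE 0.23) and Rpl11 at 0.22 (SE 0.22), and without knockout 3 were higher, by 0.18 (adjusted p = 0.00143), with a mean of -0.11 with slide row as a block (adjusted p = 0.138). In these 5 lists and the metallothionein list 0 members passed adjusted over the list alone.

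In all, 8 of 35 lists were higher and 6 lower at the preset correlation. With an estimated correlation 0 passed (camera, smallest adjusted p = 0.273). By fry 0 passed for one direction (smallest adjusted p = 0.0751), and 6 passed for change in either direction. In the simulations the estimated correlation missed a list of independent genes raised by 0.5 each time, so for such shifts a failure to pass says little. Larger shifts, such as those of the proteasome and mitosis lists, were not simulated, nor were raised lists of correlated genes. The preset correlation called 9.15 of 35 unchanged lists at a correlation of 0.3. Estimated correlations were 0.72 and 0.51 for the 20S and 19S lists, and 0.01 and 0.06 for the G1/S and G2/M lists. Of the 14 lists called, 5 kept their call without each single array, 7 with slide row as a block, and 4 in both: the 20S, 19S, G1/S and G2/M lists.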

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

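Each result was computed again under the alternatives that apply to it, 27 in all, and where a value changed the cause was not tested unless stated. The count of features higher in knockout, 0 by limma, became 1 with normexp (Hspb8), 2 with an intensity trend, 76 with array weights and 43 within slide row 2. In the last of these, a lone knockout array is assumed to vary like the controls. A probe entered that fit if it was above background on knockout 3 alone or on all control arrays. The filter thus treated the directions unequally, so counts by direction are not comparable there. The count of features lower, also 0, became 1 with quantile normalization, 1 in the deposited table (Olfr591 in both), 2 with median scaling and 2 at an adjusted p under 0.10 (Ereg and Olfr591 in both), 2 with an intensity trend, 104 with array weights and 1 within slide row 2. In all other settings, leaving out each array among them, both counts were 0. The number of lists higher in knockout, 8, became 2 with slide row as a block, 2 within slide row 2, 12 with array weights, 0 with an estimated correlation and 0 with fry; without each array in turn it ranged from 3 to 16. The number of lists lower, 6, became 10 with slide row as a block, 9 within slide row 2, 3 with array weights, 0 with an estimated correlation and 0 with fry; without each array in turn it ranged from 2 to 6. Without knockout 3 and control 1 together, an alternative chosen after seeing the data, 18 lists were higher, 5 were lower, and 0 features passed. The mean of the neutrophil list turned to -0.12 with slide row as a block and to -0.12 within slide row 2, that of NF-kappaB targets to -0.62 in both, that of Schwann cell markers to -0.49 in both, and that of the unfolded protein response to -0.23 with slide row as a block. Over the alternatives, 2079 of 2156 values of 87 named genes kept their direction and side of the threshold, 40 were newly past it and 37 moved without a call. No gene passed in the fit reported, so a value was unchanged wherever its sign held and it again failed. Some settings, such as other thresholds, cannot alter a log2 difference, and most of these genes were named for a small p. This count thus says little about stability. For lists there were 687 of 873 unchanged in direction and call, 80 no longer past the threshold, 30 newly past it and 69 that moved without a call. The log2 difference of Psmc4 was below 0 in every setting, from -1.25 to -0.70. Whether the shared replicate numbers pair the samples is not stated, and so few arrays cannot settle it. Deviations of same-numbered arrays had r of 0.07, -0.02 and 0.09 across genes, and 4 of 6 arrays correlated best with their own number. With the replicate number as a block, the counts were 0 and 0 features and 8 and 6 lists, Psmc4 differed by -0.92, and no call changed. A slide or scan date block was not run, since there was 1 of each. The largest median log2 difference of all genes under another scaling was 0.07, against 0.04 in the fit reported. Signal over background limits the weak probes: 63 features were not above background in any knockout sample and 28 in any control sample, and for these only bounds on the fold hold.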

Other observations

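The collagen family, the level of Psmc4 relative to its sister subunits, and the tests of slide row, dim arrays, loss of another cell type and fewer fibroblasts were chosen after the results were seen. Collagen genes, which encode fibrous proteins of the extracellular matrix, had lower signal in knockout cells. Among 177 families of gene symbols with at least 8 measured members, 31 collagen genes had a mean difference of -0.46, with 25 below 0 (camera, adjusted p = 3.03e-08; adjusted p = 0.987 with an estimated correlation). The family stood at -0.13, -0.27 and -0.30 in knockout 1, 2 and 3 and at 0.10, 0.18 and 0.42 in control 1, 2 and 3 (exact permutation p = 0.1, the smallest possible). Col22a1, a collagen of muscle-tendon junctions, at -1.04 (SE 0.20), and Col11a1, a fibril-forming collagen, at -1.12 (SE 0.25), were the 2 that fell adjusted over the family alone, and 0 passed over all genes. The family's mean was below 0 in every setting, from -0.53 to -0.26. The 2 other families past the threshold were the proteasome families Psmd, at 0.76, and Psmb, at 0.98 (adjusted p = 0.987 for each with an estimated correlation).

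Psmc4 moved apart from the rest of its particle. Relative to the mean of the 18 other 19S subunits on the same array, its signal was lower in knockout than in control cells by a log2 difference of -1.83 (SD 0.07 in knockout and 0.14 in control, n = 3 each; exact permutation p = 0.1, the smallest possible), or 3.56-fold. A ratio within an array shows that the change was unequal, not how much of it lay in Psmc4.

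The 32 subunits other than Psmc4 were higher in knockout cells by a mean of 0.997. Of 10000 random lists of the same size and brightness, the highest had a mean of 0.21, which argues against array scaling that depends on brightness. With slide row as a block the mean was 0.60, but as row 2 holds only 1 knockout array, the part of the shift that came with row 1 and the knockout cannot be told apart. The 10 splits of the 6 arrays are too few for a share under 0.05: 1 split, the real one, gave a mean as large, and the highest other, knockout 1 and 2 with control 1, gave 0.65. A compensatory rise of subunit mRNA in cells short of proteasomes is a candidate explanation that was not tested. Blood cells in the sort are not excluded, as their hemoglobin and neutrophil markers were higher too. With slide row as a block the neutrophil mean turned to -0.12, but Hba-a1 and Hbb-bt stayed higher, at 1.33 and 2.41.

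For the counts over all genes, the real split gave 0 features, which all 10 of 10 splits must reach, so that count decides nothing; the highest other gave 31. For lists, 2 of 10 splits gave at least the real count of 14, and the highest other gave 18; again the splits are too few for a share under 0.05. Both highest counts came from the split that sets knockout 1, knockout 2 and control 1 against the rest. It holds both arrays of slide row 1 and 2 of the 3 knockout arrays. The scans differed by row: 172 and 146 spots had outlier flags on knockout 1 and 2, and 600 to 843 in row 2. Local background was 58.8 and 58.9 on knockout 1 and 2, and 53.7 to 54.7 in row 2. Control 1, at 678 and 54.4, went with row 2. A feature count so far above the real one points to a structure of the samples, whose nature was not tested. Endothelial markers split the arrays the same way, at 0.40, 0.77 and 1.003 in knockout 1, knockout 2 and control 1. In the rest they lay between -0.92 and -0.50. Markers of macrophages, neutrophils, Schwann cells, and pericytes and smooth muscle did so too, with the same arrays above the rest. NF-kappaB targets and type I interferon genes, which are not markers of 1 cell type, also did. Markers of fibroblasts, lymphocytes, red blood cells and adipocytes did not. With slide row as a block, 0 features passed, and 2 lists were higher and 10 lower.

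The mitosis genes were lower by a mean of -1.18, and the lowest of 10000 random lists of the same size and brightness had -0.60, which argues against scaling by brightness. Without knockout 3, the array with the fewest probes above background, the mean was -1.27, which argues against that dim array as the cause. With normexp background correction the mean was -0.37. Its added offset of 50 exceeds the median processed signal of every array, at 13.8 to 22.8, and shrinks differences of weak probes. The size of the shift thus depends on this setting, and the smaller mean is no separate evidence on it. Over only the 9 members above background on all 6 arrays, without that offset, the mean was -0.27 and the call ended. That filter drops genes whose lower level took them below background. Much of the list's mean thus came from members with weak probes, for which the size of the change is uncertain. Loss of a dividing cell type from the knockout sort stays open, as such a type need not have a list here, and the lowest marker list, of fibroblasts, had a mean of -0.20 (with slide row as a block the lowest was endothelial, at -0.61, beside -0.997 for mitosis). Fewer cycling satellite cells in the knockout is a candidate explanation that was not tested.

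For the collagen genes, the lowest random list of the same size and brightness had a mean of -0.29, against the observed -0.46, which argues against scaling by brightness. The 15 fibroblast markers that are not collagens had a mean of -0.12 (SE 0.09 over markers), above the collagen mean by more than 2 standard errors. Such a standard error is over genes of the same arrays and does not measure the spread between mice. With slide row as a block the markers were at -0.37 (SE 0.09) and the collagens at -0.53, a gap within 2 standard errors, so fewer fibroblasts in the knockout sort stay open. Lower matrix production by knockout satellite cells may be a cause and was not tested.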
